A study of Mus musculus with 8 samples.

How the data were processed

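RNA was sequenced from cells of mouse epidermis that carried the label of an Lgr5 reporter, a genetic mark of hair follicle stem cells and their progeny, and that had been sorted by flow cytometry after injury to the skin barrier. The labels give 8 libraries in 2 conditions, with regulatory T cells (Treg-sufficient, n = 4) or without them (Treg-depleted, n = 4), and an experiment number, 1 or 2. Each experiment holds 2 libraries of each condition: replicates 1 and 2 of a condition belong to experiment 1 and replicates 3 and 4 to experiment 2. How and when the regulatory T cells were removed, how the skin was injured and how long after injury the cells were taken are not given in the sources used here. The labels do not say whether replicates came from separate animals, so the p-values measure the spread between these samples, part of which may be technical.

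The authors deposited a table of read counts per gene, with no normalization, for all 8 libraries. Per the labels' protocols, sorted cells were flash frozen, RNA was isolated on RNeasy columns and libraries were made with the TruSeq Stranded mRNA kit, which selects polyadenylated RNA and keeps the strand of origin. Per the submitters' processing notes, the tools named are TopHat2 (version 2), SAMtools, HTSeq and DESeq2 and the genome build is GRCm38.p4, without the role of each tool. The strand setting of the counting and the annotation release are not given in the sources used here. The deposited counts were whole numbers with different totals per library, and the table held no fold changes or p-values, although its name speaks of differential expression results. It listed 46078 genes by Ensembl identifier and 5 tallies of reads not given to a gene. Those tallies were kept out of library sizes and tests. Of all reads listed, reads in no annotated gene made up 6.63 to 10.8%, reads overlapping several genes 2.72 to 3.01% and reads aligned to several places 26.2 to 30.6%, while the tallies of unaligned and of low-quality reads were 0. Reads aligned to several places were therefore not counted for any gene, so that values of genes with near-identical copies (classical and Qa class I histocompatibility genes, keratins, Hspa1a and Hspa1b, globins) are uncertain.

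Library totals over genes were 27263384, 28850186, 26608260 and 29975347 counts in Treg-sufficient replicates 1 to 4 and 29623892, 22330729, 24775026 and 27700542 in Treg-depleted replicates 1 to 4. At these depths counting error was small beside the spread between libraries for all but the lowest genes. Symbols and coordinates were taken from the GENCODE M21 annotation of GRCm38, which paired 45143 of the identifiers with a symbol. It may differ from the release used for counting. No count was recorded for 18467 genes, and 16495 genes passed edgeR's filterByExpr (minimum count 10) and were tested. They held at least 99.89% of the counts of each library.

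Differences were tested in R 4.3.3 with edgeR 4.0.16, using TMM factors and the quasi-likelihood F-test, and Benjamini-Hochberg adjustment over the 16495 genes with a threshold of 0.05. The model for the difference between conditions had terms for condition and experiment number and 5 residual degrees of freedom, and its experiment term gave the difference between experiments. A second model with 4 groups of 2 libraries (4 residual degrees of freedom) gave the effect within each experiment and their difference, the interaction. In that model a group of 2 is assumed to vary like the others, which the pairs of libraries described below did not do. Log2 fold changes are given with their standard error (SE), and levels as CPM on TMM-scaled library sizes with mean ± SD. Summed CPM of cell type markers and the Xist and Y-linked levels use unscaled library totals instead. The marker sums also take in listed genes that were not tested. The same steps were tested on simulated counts for the 16495 genes. Counts were drawn independently for each gene, with no outlying library and no difference between libraries other than depth and the simulated changes. The changed genes all had a mean normalized count of at least 50, so the shares recovered do not cover lower genes. Between conditions, 66% of genes changed by 1 log2 unit and 95% of those changed by 2 were recovered. The corresponding shares were 19% and 89% within experiment 1, 20% and 91% within experiment 2 and 2% and 59% for the interaction. Between experiments they were 69% and 97%. Unchanged genes made up 10.3% of the calls for the interaction, above the threshold of 0.05, and 4.05 to 5.93% in the other comparisons. With no gene changed, 0 genes were called between conditions.

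Before the data were examined, 21 gene lists for skin and 9 lists of markers of other cell types were fixed, with the tests, the alternatives and the rule for naming genes. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, again with the correlation estimated for each list, and with fry, each adjusted over the 30 lists. In a simulation all 10 shifted lists were found and 0 of 20 unshifted lists were called at either correlation. Its genes were drawn independently, so it could not show false calls that arise when members of a list vary together. A list score is the mean over its members of log2 CPM centred on the mean of the 8 libraries. Library measures and summed CPM of cell type markers (16 in all) were compared by two-sided exact permutation tests, 4 against 4, over 70 assignments, whose smallest possible p is 0.0286. Added after seeing the data were the same tests with libraries exchanged within their experiment alone, where 36 assignments allow no p below 0.0556, so that 0.05 cannot be passed. Genes named in the text are 10 fixed genes (Lgr5, Cd34, Krt15, Sox9, Cxcl5, Il17ra, Krt10, Ivl, Foxp3, Ptprc). To these come the 10 largest changes each way among genes past the threshold that had a mean normalized count of at least 50 and moved the same way in both experiments, and up to 4 members of each list past the threshold. Moving the same way means an equal sign, with no minimum size. Where fewer than 10 genes passed, the 10 smallest p-values were taken instead. For a list called between conditions with no member past the threshold, the rule took its 2 most highly expressed members. Some of these are not described with their lists below. For the difference between experiments, the same direction in both conditions took the place of the same direction in both experiments. Any other gene is said to have been chosen after its values were seen.

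Of the named genes, 120 were checked for overlap with other annotated genes, and 13 shared over 10% of their exonic length: Ccn2, Ccnd1, Cebpd, Cish, Crispld1, Dnajb13, Foxp3, Hmgcs1, Jund, Mt2, Penk, S100a4 and Tagln. Because the strand setting is unknown, reads of these genes and of their partners may not have been told apart. Reads in the shared stretches may then have been lost to the tally of reads overlapping several genes. The largest overlaps were 73.5% for Mt2, 67.9% for Tagln and 52.6% for Jund on the opposite strand and 51.7% for S100a4 on the same strand.

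No pair of libraries agreed within sampling noise, the smallest chi-square per degree of freedom between any pair being 22.6, and all were used. It was 92.2 for the Treg-depleted pair of experiment 1 and 24.1 for that of experiment 2. For the Treg-sufficient pairs of experiments 1 and 2 it was 42.6 and 49.8. The 4-group model nevertheless shares its spread over all of these groups. Whether the experiment number marks a shared batch was checked from each library's deviation from its condition mean. Libraries of the same experiment in different conditions had a mean correlation of 0.227. It was the highest of the 18 ways to put 2 libraries of each condition together, the highest other being 0.069. The alternatives tried were a model without the experiment number, a model with the letters of the library names as pairs, DESeq2 1.42.0, limma-voom, other scaling factors, other filters and thresholds, each experiment alone and leaving out each library. Added after seeing the data were fits without both libraries that held Xist reads, the mean effect from the 4-group model, the medians of lists between conditions and the lists within and between experiments with each library left out. The libraries named for Xist reads are Treg-sufficient replicate 2 and Treg-depleted replicate 2, whose Xist level stood far above that of the others.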

Results

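Lgr5-traced cells of the hair follicle were profiled by RNA sequencing after injury to the skin barrier, in mice with regulatory T cells (Treg-sufficient, n = 4 libraries) and without them (Treg-depleted, n = 4). Lgr5 marks stem cells of the lower follicle, and tracing also keeps the mark in their progeny. The 8 libraries came from 2 experiments with 2 libraries of each condition in each, and totals over genes ran from 22330729 to 29975347 counts. Nothing in the labels says that replicates came from separate animals, so the p-values measure the spread between these samples. The deposited values were raw read counts, tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 16495 genes. Levels are CPM, given as mean ± SD.

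The libraries were not alike in sex-linked transcripts. Xist, which is expressed from the inactive X chromosome of female cells (ENSMUSG00000086503, GRCm38 chromosome X, 103460366 to 103483254, minus strand, a long non-coding RNA), stood at 2713 CPM of the library total in Treg-sufficient replicate 2. It stood at 72 CPM in Treg-depleted replicate 2 and between 0.968 and 2.26 CPM in the other 6 libraries. Summed Y-linked transcripts were 2.84 CPM in Treg-sufficient replicate 2 and 314 to 417 CPM in the other 7 libraries. Treg-sufficient replicate 2 and Treg-depleted replicate 2, called the libraries that held Xist reads for their raised level, both belong to experiment 1. Treg-depleted replicate 2 also held counts for fewer genes (18605) than the other Treg-depleted libraries (22670 to 23062), at the lowest total of the 8 libraries. Treg-sufficient replicate 3 held 19593, against 21720 to 22789 in the other Treg-sufficient libraries, though its total exceeded that of Treg-depleted replicate 3. The number of genes thus did not follow the total alone. Treg-sufficient replicate 3 and Treg-depleted replicate 2 also had the lowest shares of reads in no annotated gene (6.70 and 6.63%). Their epidermal terminal differentiation scores were the lowest too (-1.128 and -0.818).

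**Figure D1:**
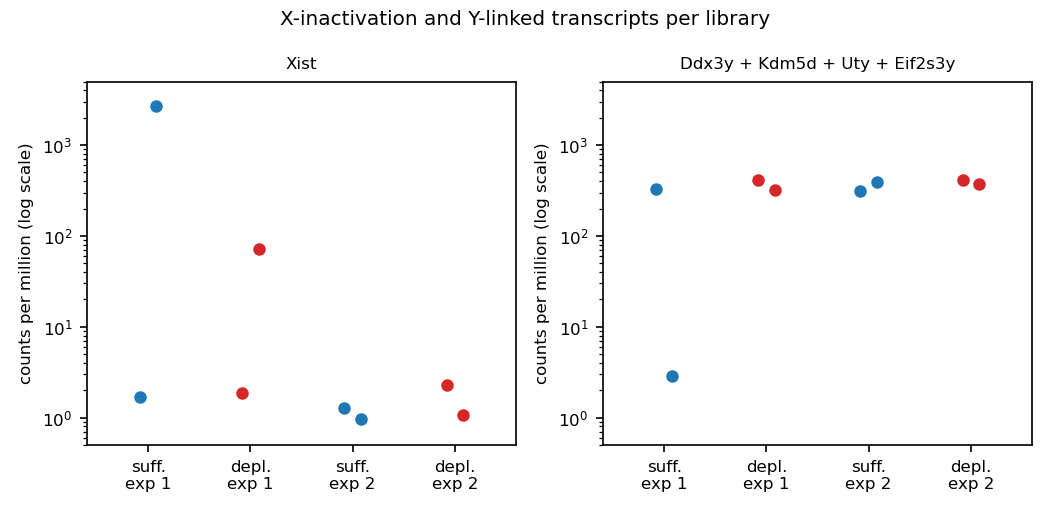
Xist and the sum of the Y-linked transcripts in each of the 8 libraries, in CPM on a log axis, with each point a library and colour the condition. Treg-sufficient replicate 2 combines the highest Xist level (2713 CPM) with the lowest Y-linked sum (2.84 CPM), and Treg-depleted replicate 2 holds 72 CPM of Xist beside a Y-linked sum of 316 CPM.

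The first comparison asked what the absence of regulatory T cells changes in follicle stem cells and their progeny after injury. As groups, immediate early genes were higher in Treg-depleted libraries, and genes of hair lineage differentiation and of the cell cycle were lower, in the set test at a preset correlation. With an estimated correlation these 3 lists had an adjusted p of 0.410, 0.331 and 0.488, and 0 of 30 lists passed. Egr1, a transcription factor that responds to growth factors and stress, averaged 997 ± 319 CPM in Treg-depleted against 355 ± 191 CPM in Treg-sufficient libraries (n = 4 each). Mki67, a marker of cycling cells, averaged 587 ± 428 against 918 ± 234 CPM. Genes of stem cell identity as a group did not pass, and Lgr5 itself stood at 444 ± 92.8 against 421 ± 57.5 CPM. No single gene passed an adjusted p of 0.05.

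By edgeR 0 of 16495 genes passed between conditions (smallest adjusted p = 0.686), and 1175 had an unadjusted p under 0.05. Of these 578 were higher and 597 lower, where chance gives 825 in all. DESeq2 called 90 genes (54 higher, 36 lower), limma-voom 0, and edgeR without the filter on low counts 820 (339 higher, 481 lower). The 10 genes with the smallest p had an adjusted p of 0.686 each. In all of them the 4 Treg-depleted libraries lay beyond both Treg-sufficient libraries of their own experiment. This separation is no added support, since the genes were chosen for their p. Apcdd1, a membrane inhibitor of Wnt signalling (ENSMUSG00000071847, chromosome 18, 62922231 to 62961179, plus strand), averaged 38.6 ± 8.07 CPM in Treg-depleted and 74.9 ± 9.49 CPM in Treg-sufficient libraries (log2 fold change -0.97, SE 0.14, unadjusted p = 9.02e-05). It was joined on the lower side by Mycl, a transcription factor of the Myc family (-0.99), Mt4, a metallothionein of stratified epithelia (-2.20), and Lzts1 (-0.96). On the higher side were the circadian repressor Nr1d1 (1.61; 39.6 ± 27.6 against 12.3 ± 4.93 CPM), the transcriptional repressor Bcl6 (0.65), Fam13a (1.11), the lipid phosphatase gene Plpp3 (0.53), the small Maf factor Mafk (0.69) and Tmem204 (2.50, at no more than 1.1 CPM in any library).

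**Figure D2:**
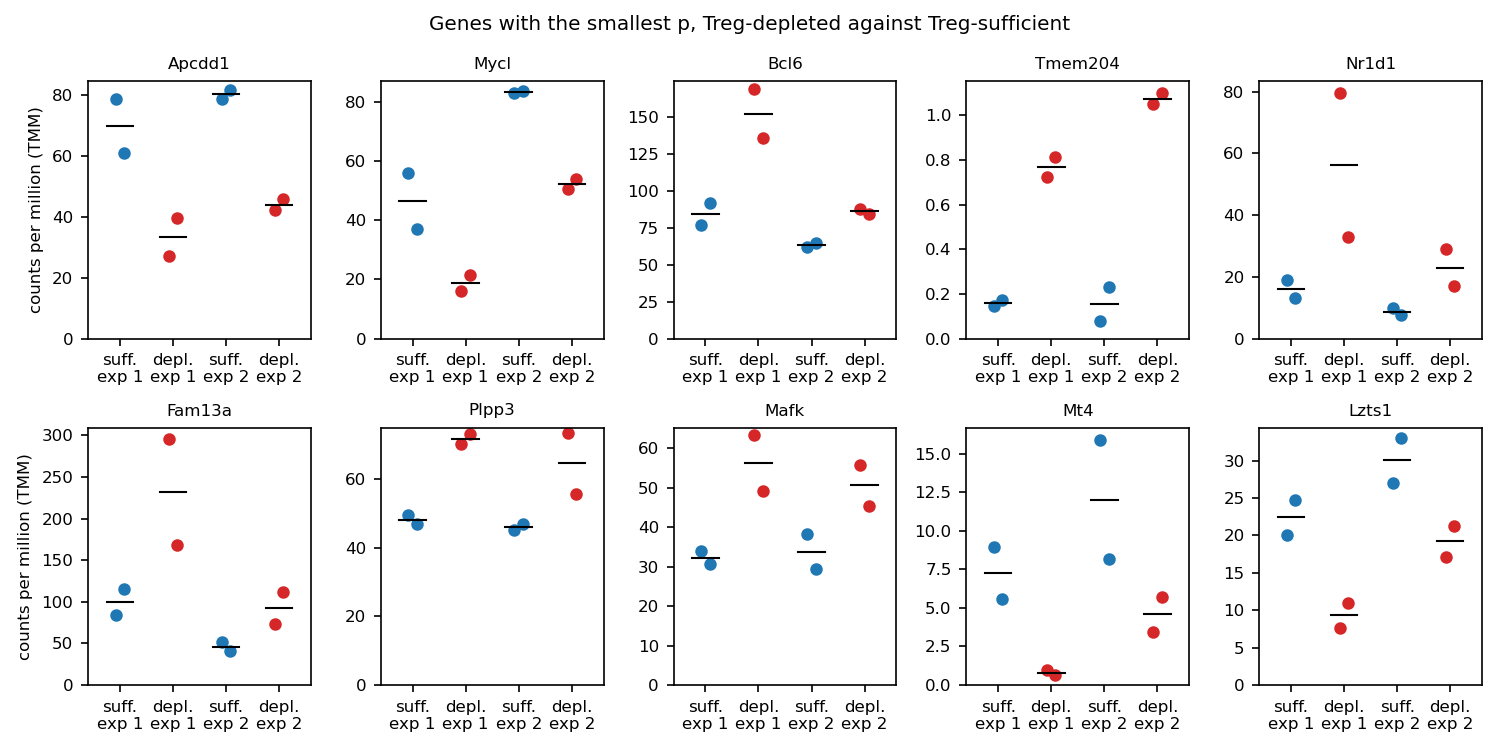
Levels of the 10 genes with the smallest p between conditions, in CPM, for each of the 8 libraries, with blue points for Treg-sufficient and red for Treg-depleted libraries, columns for the experiments and black bars for the mean of 2 libraries. For Apcdd1 the Treg-depleted libraries sit between 27.2 and 45.7 CPM and the Treg-sufficient libraries between 60.8 and 81.6 CPM, and the adjusted p of each gene is 0.686.

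Immediate early and dissociation stress genes, which cells switch on within minutes of a stimulus, formed the group with the largest median shift. All 22 measured members were higher in Treg-depleted libraries (median log2 fold change 1.14, camera adjusted p = 6.90e-31 over 30 lists). The adjusted p was 0.410 with an estimated correlation and 0.302 by fry. None of them passed over all genes and 22 passed when adjusted over the list alone. Fos, the most highly expressed member, stood at 1630 ± 487 against 611 ± 347 CPM (log2 fold change 1.49, SE 0.53, adjusted p = 0.686) and Egr1 had a log2 fold change of 1.56 (SE 0.40, adjusted p = 0.686).

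The cell cycle list was lower (median -0.79, adjusted p = 2.41e-23; adjusted p = 0.488 with an estimated correlation and 0.436 by fry). All 38 members had negative values, 0 passed over all genes and 0 adjusted over the list alone. The most abundant were Mki67 (-0.97, SE 0.36) and Top2a (-0.67, SE 0.30), both at adjusted p of 0.686 or above. Hair lineage differentiation, made of keratins of the hair shaft and inner root sheath and of their regulators, was lower too (median -0.85, adjusted p = 4.29e-12; adjusted p = 0.331 with an estimated correlation and 0.302 by fry). Of its 15 measured members 14 were negative. Of these 6 were lower when adjusted over the list alone against 0 over all genes. Among these 6, chosen after their values were seen, were Dlx3 and Msx2, regulators of hair shaft formation, and the keratin genes Krt35 and Krt28. The 2 most highly expressed members, the transcription factor genes Gata3 (0.09, SE 0.16) and Hoxc13 (-0.26, SE 0.16), were close to 0. These 3 lists and cholesterol synthesis were called by camera at the preset correlation with any single library left out. Without Treg-depleted replicate 1 the cell cycle median was -0.46, and without Treg-depleted replicate 3 the hair lineage median was -1.31.

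**Figure D3:**
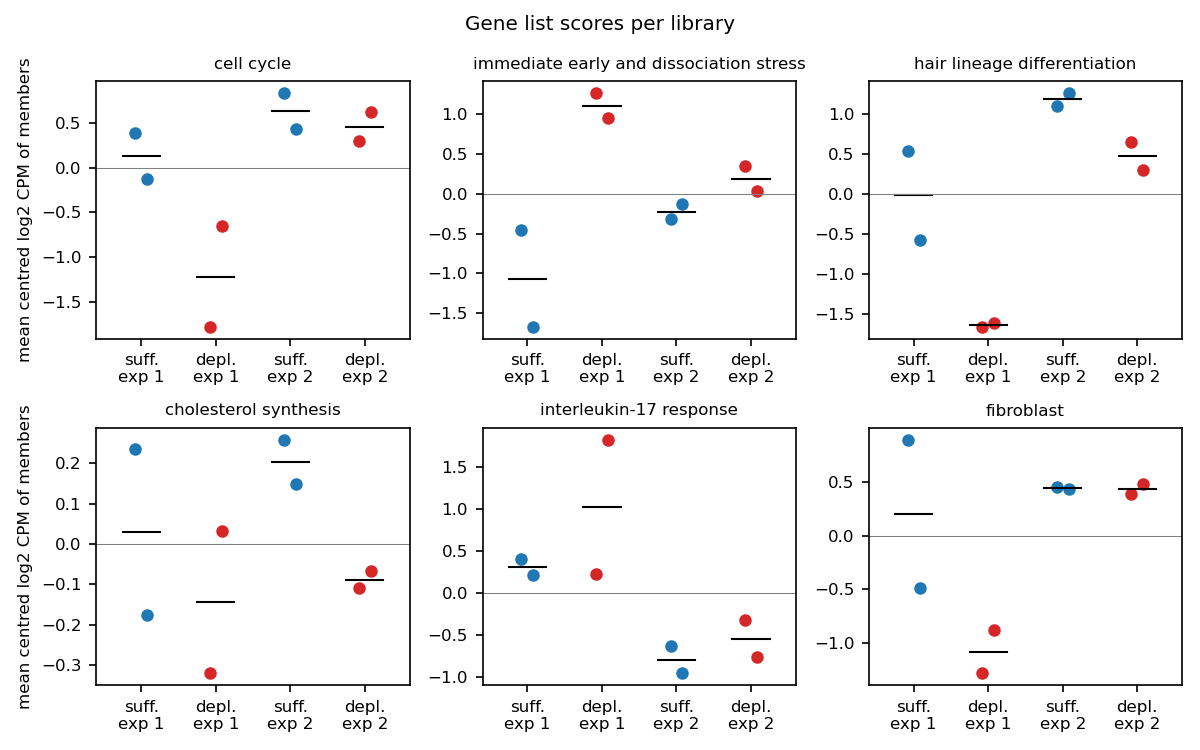
Scores of 6 gene lists in the 8 libraries, as the mean over members of log2 CPM centred on the mean of all libraries, with points for libraries, bars for the mean of the 2 libraries of a condition in an experiment, blue for Treg-sufficient and red for Treg-depleted. On average the immediate early list is higher and the cell cycle and hair lineage lists lower in the Treg-depleted libraries. The adjusted p of these lists is 0.331 or above when the correlation is estimated. In experiment 2 the cell cycle scores overlap, at 0.292 and 0.624 in Treg-depleted and 0.83 and 0.433 in Treg-sufficient libraries.

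Cholesterol synthesis enzymes were slightly lower as a group (median -0.23, adjusted p = 2.62e-05; adjusted p = 0.579 with an estimated correlation). Under TMM 18 of 21 members were negative, against 20 with DESeq2 size factors and 21 with upper-quartile factors. Hmgcs1, which makes the substrate of the pathway's rate-limiting enzyme, stood at 288 ± 50 against 358 ± 51.8 CPM. Interleukin-17 response genes were higher (median 0.73, 14 of 15 positive, adjusted p = 0.00306; adjusted p = 0.488 with an estimated correlation). Nfkbiz, a co-activator of the response, stood at 103 ± 36.8 against 50.5 ± 12.8 CPM (0.98, SE 0.28, adjusted p = 0.686). Steap4 stood at 345 ± 172 against 235 ± 45.4 CPM. Antigen presentation genes were higher for MHC class II (median 0.75, 8 of 8 positive, adjusted p = 0.00433; adjusted p = 0.579 with an estimated correlation). They were higher for class I too (median 0.17, adjusted p = 0.0234; adjusted p = 0.856 with an estimated correlation). The 14 positive values of class I became 11 under DESeq2 size factors and 11 under upper-quartile factors. B2m, its most highly expressed member, stood at 465 ± 140 against 467 ± 154 CPM. In each of these 4 lists 0 members passed over all genes and 0 adjusted over the list alone. The cholesterol median was -0.13 without Treg-depleted replicate 1. The interleukin-17 call ended without Treg-depleted replicate 2 (median 0.05, adjusted p = 0.273) and without both libraries that held Xist reads (0.457), and the median was 0.43 without Treg-sufficient replicate 1. The class II call ended without Treg-depleted replicate 1 (median 0.35, adjusted p = 0.136), and the median was 0.48 without Treg-sufficient replicate 1. The class I call ended without Treg-sufficient replicate 1 (median 0.06, adjusted p = 0.478), without Treg-depleted replicate 1 (0.05, 0.474) and without the experiment number in the model (0.0916), and the median was 0.29 and 0.28 without replicate 2 of Treg-sufficient and Treg-depleted.

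Markers of other cell types were measured beside these groups. Fibroblast markers were lower in Treg-depleted libraries (8 of 9 negative, median -0.59, adjusted p = 0.00510; adjusted p = 0.488 with an estimated correlation). So were endothelial markers (5 of 5 negative, median -0.89, adjusted p = 0.0234; adjusted p = 0.410 with an estimated correlation). In both lists 0 members passed over all genes and 0 adjusted over the list alone. Of 14 alternatives the fibroblast call held in 9 and the endothelial call in 5. Both ended by fry and without Treg-depleted replicate 1 (adjusted p = 0.0797 and 0.109), Treg-depleted replicate 2 (0.0748 each) or both libraries that held Xist reads (0.0509 and 0.174). The endothelial call also ended without Treg-sufficient replicate 2 (0.0804) or 3 (0.0711), in the 4-group model (0.0555) and over genes with a mean normalized count of at least 50 (0.552). The fibroblast median was -0.98 without Treg-sufficient replicate 4 and -0.39 without Treg-depleted replicate 1, and the endothelial median -0.43 without Treg-sufficient replicate 3. Summed fibroblast markers were 261 ± 67.4 against 356 ± 64.1 CPM (n = 4, two-sided exact permutation p = 0.114, adjusted p = 0.456 over 16 measures, and p = 0.111 with exchange within experiments alone). Summed endothelial markers were 6.93 ± 2.29 against 10.5 ± 2.39 CPM (two-sided exact permutation p = 0.0857, adjusted p = 0.456, and p = 0.111 within experiments). The other 7 cell type lists did not pass: the adjusted p was 0.143 for muscle, 0.209 for regulatory T cell, 0.236 for melanocyte, 0.274 for T cell, 0.737 for macrophage and Langerhans cell, 0.895 for red blood cell and 0.983 for neutrophil markers. Regulatory T cell markers summed to 48.6 ± 21.7 CPM in Treg-depleted and 36.7 ± 8.78 CPM in Treg-sufficient libraries (n = 4, two-sided exact permutation p = 0.400, adjusted p = 0.914, and p = 0.0556 within experiments, the smallest possible there), with 4 of 4 log2 fold changes positive. T cell markers summed to 18.0 ± 5.09 against 18.4 ± 4.27 CPM. Macrophage and Langerhans cell markers summed to 4.52 ± 1.55 against 5.03 ± 1.15 CPM, and neutrophil markers to 5.07 ± 2.20 against 5.79 ± 1.38 CPM. Foxp3, the defining transcription factor of regulatory T cells, had 0 to 22 counts per library in both conditions (0.46 ± 0.32 against 0.47 ± 0.28 CPM). In libraries of sorted follicle cells these marker values can neither support nor refute the depletion that the labels give. Ptprc, the pan-leukocyte marker, had at most 11 counts, too few to test.

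The fixed genes and the other lists between conditions gave values near 0 or wide spreads. Cd34, a marker of bulge stem cells, stood at 348 ± 225 against 171 ± 105 CPM (log2 fold change 1.06, SE 0.33, unadjusted p = 0.0114, adjusted p = 0.686). In 3 of 4 Treg-depleted libraries it was above both controls of their experiment. Krt15, the bulge keratin, had a log2 fold change of -0.06 (SE 0.21), and the stem cell regulator Sox9 0.00 (SE 0.16, turning to -0.01 under DESeq2 size factors and upper-quartile factors). Il17ra, the interleukin-17 receptor chain, had 0.23 (SE 0.13), and the differentiation genes Krt10 and Ivl had -0.28 (SE 0.61) and -0.08 (SE 0.51). The neutrophil chemokine gene Cxcl5 had 0 to 9 counts per library and was not tested. Stem cell identity (median 0.04, adjusted p = 0.274), epidermal terminal differentiation (median 0.09, adjusted p = 0.895), the wound-activated keratinocyte list (median -0.14, adjusted p = 0.647), the interferon response (median 0.27, adjusted p = 0.108) and the Notch list (median -0.01, adjusted p = 0.959) did not pass. Nor did basal keratinocyte (adjusted p = 0.143), upper follicle (0.431), sebaceous (0.274), BMP and TGF-beta (0.541), neutrophil chemokine (0.647), glycolysis and hypoxia (0.541), migration and matrix (0.737) or mitochondrial oxidative phosphorylation genes (0.541). In the BMP and TGF-beta list 1 member was higher and 2 lower adjusted over the list alone against 0 over all genes. The Wnt list did not pass for direction (adjusted p = 0.895), had 2 members higher and 1 lower adjusted over the list alone against 0 over all genes. It passed fry's test for change in either direction (adjusted p = 0.0498). That test passed 1 of 30 lists between conditions, 11 in experiment 1, 0 in experiment 2, 0 for the interaction and 15 between experiments. The 3 Wnt members, chosen after their values were seen, were Wif1 and Lgr6 on the higher and Apcdd1 on the lower side.

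Within experiment 1, where the question is what the depletion changes in each experiment taken by itself, immediate early genes were higher and cell cycle, hair lineage and fibroblast marker genes lower as groups in Treg-depleted cells, at the preset correlation of the set test. With an estimated correlation the adjusted p of these lists was 0.157, 0.407, 0.286 and 0.157. Serpina3n, a secreted protease inhibitor of the acute phase (ENSMUSG00000021091, chromosome 12, 104406729 to 104414329, plus strand), rose from 10.1 ± 7.13 to 598 ± 497 CPM (n = 2 each; log2 fold change 5.89, SE 0.76, edgeR adjusted p = 0.0257). Krt35, a keratin of the hair cortex (ENSMUSG00000048013, chromosome 11, 100092193 to 100096241, minus strand), fell from 7.19 ± 4.17 to 0.103 ± 0.146 CPM (-5.88, SE 0.82, edgeR adjusted p = 0.0336). Over 16 alternatives its log2 fold change kept its direction but ran from -10.604 to -5.126. In all 100 genes passed, 37 higher and 63 lower, and 1824 had an unadjusted p under 0.05 where chance gives 825.

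Among the largest increases in experiment 1 were Cebpd, a transcription factor of the acute-phase response (log2 fold change 3.49, SE 0.36), the monocyte chemokine gene Ccl7 (3.08, SE 0.46), and Tsc22d3, a classical glucocorticoid-induced gene (2.98, SE 0.30). The feedback inhibitors of growth factor and cytokine signalling Errfi1 (2.61), Dusp1 (2.46) and Cish (2.38) rose as well, followed by Clu (2.22) and Tent5b (2.16). The rule for naming these largest changes asked for the same sign in experiment 2 but not for any size there. Errfi1, for example, had 0.04 in experiment 2. Of the immediate early list 7 of 22 members rose over all genes and 22 adjusted over the list alone (camera adjusted p = 2.07e-56; adjusted p = 0.157 with an estimated correlation and 0.0462 by fry). Egr1 (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984, plus strand) rose from 216 ± 43.1 to 1250 ± 213 CPM (n = 2 each; 2.54, SE 0.28, edgeR adjusted p = 0.0167). Ier2 (1.80), Jund (1.34) and the small heat shock protein gene Hspb1 (1.29) rose too. The interleukin-17 list was higher (median 1.33, adjusted p = 1.88e-04; adjusted p = 0.407 with an estimated correlation) through 1 member over all genes, Zc3h12a (1.33), and 3 adjusted over the list alone. Irf1 rose (1.44) in an interferon list that did not pass (adjusted p = 0.311). MHC class I genes were higher (11 of 14 positive, 10 with upper-quartile factors, median 0.17, adjusted p = 0.00955; adjusted p = 0.687 with an estimated correlation). Of them 0 passed over all genes and 3 adjusted over the list alone. The interleukin-17 call ended without Treg-depleted replicate 2 (median 0.19, adjusted p = 0.142). The class I call ended, with a median below 0, without Treg-sufficient replicate 1 (-0.11, adjusted p = 0.767) or Treg-depleted replicate 1 (-0.18, adjusted p = 0.753), and the median was 0.52 without Treg-sufficient replicate 2 and 0.49 without Treg-depleted replicate 2.

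The cell cycle list had the smallest p among the lower lists of experiment 1 (38 of 38 negative, median -1.42, adjusted p = 5.14e-39; adjusted p = 0.407 with an estimated correlation). Of its members 3 were lower over all genes and 27 adjusted over the list alone. The 3 were Cenpf (-2.0, SE 0.19; 34.6 ± 6.52 against 138 ± 19.4 CPM, n = 2), Cenpa (-1.70) and Ccnb2 (-2.11), genes of the centromere and of mitotic entry. The mitotic kinesin gene Kif23 (-2.39) and Pimreg (-2.44) outside the list fell as well. Hair lineage genes fell as a group (median -1.24, adjusted p = 5.07e-10; adjusted p = 0.286 with an estimated correlation), 1 over all genes and 8 adjusted over the list alone. Epidermal terminal differentiation genes were lower (25 of 34 negative, 26 with upper-quartile factors, median -0.50, adjusted p = 3.83e-04; adjusted p = 0.676 with an estimated correlation) with 0 over all genes and 3 adjusted over the list alone. Fibroblast markers were lower (8 of 9 negative, 9 with the other scaling factors, median -1.57, adjusted p = 2.45e-06; adjusted p = 0.157 with an estimated correlation). Col5a1, a fibrillar collagen gene, passed over all genes (-1.67, SE 0.15) and 4 members passed adjusted over the list alone. Smooth and skeletal muscle markers passed by fry (2 of 2 negative, median -1.87, adjusted p = 0.0462) and not by camera (adjusted p = 0.0846; adjusted p = 0.407 with an estimated correlation), with 0 over all genes and 1 adjusted over the list alone. Their scores were -1.886 and -1.173 in Treg-depleted against 0.194 and 0.557 in Treg-sufficient libraries, at low levels. Summed, they stood at 1.55 and 8.73 CPM in Treg-depleted replicates 1 and 2, against 6.93 and 9.32 CPM in the controls. In the sum Treg-depleted replicate 2 thus lay between the controls. Other large decreases were those of the urea cycle enzyme gene Cps1 (-5.07), Mt4 (-3.17), the proenkephalin gene Penk (-3.15), Dnajb13 (-3.07), Fam163b (-2.85), Tspear (-2.79) and Nrep (-2.44). The cell cycle median was -0.98 (36 of 38 negative) without Treg-depleted replicate 1 and -2.19 without Treg-depleted replicate 2. That of hair lineage genes was -1.89 without Treg-sufficient replicate 2 and -2.14 without Treg-depleted replicate 2, and that of fibroblast markers -0.86 without Treg-sufficient replicate 1. The epidermal call ended without Treg-sufficient replicate 2 (adjusted p = 0.252) or Treg-depleted replicate 2 (0.0583), and its median was -0.86 without Treg-sufficient replicate 1 and -1.24 without Treg-depleted replicate 1.

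The count of 100 genes in experiment 1 moved with the libraries used: it was 34, 23, 24 and 23 without Treg-sufficient replicates 1 to 4 (22, 2, 8 and 8 of them higher), and 59, 442, 0 and 16 without Treg-depleted replicates 1 to 4 (19, 142, 0 and 5 higher). Most genes were therefore higher, not lower, without Treg-sufficient replicate 1, and so they were with limma-voom (82 genes, 43 higher and 39 lower). The 4 libraries of experiment 1 fitted alone gave 0 genes. The count was 487 (135 higher, 352 lower) without both libraries that held Xist reads, a fit that leaves 1 library per condition in experiment 1 and takes the spread from experiment 2 alone. It was 708 (231 higher, 477 lower) with DESeq2 and 1152 (393 higher, 759 lower) without the filter on low counts. The Treg-depleted pair of experiment 1 differed more (chi-square per degree of freedom 92.2) than that of experiment 2 (24.1). For the Treg-sufficient pairs it was 42.6 and 49.8. Since the model shares its spread, that of Treg-depleted libraries may be understated in experiment 1 and overstated in experiment 2. The counts of genes in the 2 experiments are therefore hard to compare.

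In experiment 2 the depletion left no gene past the threshold. By edgeR 0 genes passed (smallest adjusted p = 1), 288 had an unadjusted p under 0.05, fewer than the 825 that chance gives, DESeq2 called 2, limma-voom 0 and edgeR without the filter on low counts 132. Hair lineage genes were again lower as a group (15 of 15 negative, median -0.81, camera adjusted p = 3.87e-08; adjusted p = 0.856 with an estimated correlation). Krt35 stood at 8.11 ± 2.84 against 27.0 ± 6.95 CPM (n = 2 each). Epidermal terminal differentiation genes were higher (26 of 34 positive, median 0.76, adjusted p = 1.36e-10; adjusted p = 0.856 with an estimated correlation), with 0 over all genes and 1 adjusted over the list alone. The smallest p belonged to Cdsn, which encodes corneodesmosin of the cornified layer (10.4 ± 2.82 against 2.37 ± 0.44 CPM, log2 fold change 2.12, SE 0.39). Immediate early genes were higher (19 of 22 positive, 20 with upper-quartile factors, median 0.48, adjusted p = 4.46e-06) and cholesterol synthesis genes lower (20 of 21 negative, median -0.27, adjusted p = 6.47e-08), each at adjusted p = 0.856 with an estimated correlation. The cell cycle list was lower by a median of -0.19 (adjusted p = 0.0127; adjusted p = 0.875 with an estimated correlation). Stem cell identity genes were higher (14 of 20 positive, 16 with upper-quartile factors, median 0.10, adjusted p = 0.0350; adjusted p = 0.856 with an estimated correlation). Wound-activated keratinocyte genes were lower (median -0.15, adjusted p = 0.00910; adjusted p = 0.856 with an estimated correlation). In these 6 lists other than epidermal terminal differentiation 0 members passed over all genes and 0 adjusted over the list alone. The cell cycle call ended without Treg-sufficient replicate 3 (median 0.02, adjusted p = 0.839) or Treg-depleted replicate 3 (-0.03, 0.924), and the median was -0.37 and -0.36 without replicate 4 of either condition. The stem cell call ended without Treg-sufficient replicate 3 (0.16, 0.124), Treg-sufficient replicate 4 (0.17, 0.180) or Treg-depleted replicate 3 (0.05, 0.624). The wound call ended without Treg-sufficient replicate 4 (0.15, 0.555) or Treg-depleted replicate 4 (-0.15, 0.0942), and its median was -0.55, -0.31, -0.32 and -0.77 without Treg-sufficient replicate 3 and Treg-depleted replicates 1, 2 and 3. Without Treg-depleted replicate 3 the epidermal median was 0.42 and the immediate early median 0.27. The epidermal median was 0.55 without Treg-sufficient replicate 3, the library with the lowest epidermal score.

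Other genes among the 10 smallest p-values of experiment 2, all at an adjusted p of 1, were Apcdd1 (log2 fold change -0.87), the metallothionein gene Mt2 (-1.39), the Wnt ligand genes Wnt10b (-1.03) and Wnt8a (-3.27), the cornified envelope gene Crct1 (4.90), Pde4a (1.92), Bco2 (-2.98), Clec2e (-3.26) and the interleukin-22 decoy receptor gene Il22ra2 (6.66). Crct1, Bco2, Clec2e, Wnt8a and Il22ra2 were near the limit of detection, with mean normalized counts of 27.4, 18.0, 18.3, 10.4 and 9.04.

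The effects of the 2 experiments were compared directly by their interaction. The smallest p belonged to Col14a1, a fibril-associated collagen gene, which stood at 17 ± 4.16 against 171 ± 40.1 CPM in experiment 1 and at 457 ± 96.2 against 403 ± 14.4 CPM in experiment 2 (Treg-depleted against Treg-sufficient, n = 2 each; interaction 3.51, SE 0.35, edgeR adjusted p = 0.135). No gene passed by edgeR, 923 had an unadjusted p under 0.05 where chance gives 825, DESeq2 called 186, limma-voom 0 and edgeR without the filter 534. The other genes among the 10 smallest p were Col5a1 (1.72), Plekhg1 (1.61), the mitotic genes Kif14 (2.25), Cenpf (1.98), Aspm (1.93) and Kif23 (2.30), Nrep (2.44), Crispld1 (2.19) and Ier2 (-1.91), at adjusted p of 0.135 or 0.148. The count was 9 (0 positive, 9 negative) without Treg-sufficient replicate 1 and 89 (78 positive, 11 negative) without both libraries that held Xist reads, with 1 library per condition left in experiment 1 and the spread taken from experiment 2 alone.

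As groups, 7 lists differed in their response between experiments at the preset correlation and 0 with an estimated one. The cell cycle (median interaction 1.19, 38 of 38 positive, adjusted p = 7.05e-25), epidermal terminal differentiation (1.67, 30 of 34, adjusted p = 6.61e-13) and hair lineage lists (0.78, adjusted p = 0.00450) had more positive effects in experiment 2, each at adjusted p = 0.590 with an estimated correlation. The same held for fibroblast markers (1.71, 9 of 9, adjusted p = 1.05e-05; adjusted p = 0.330 with an estimated correlation). More negative effects in experiment 2 were found for immediate early (-1.73, 22 of 22 negative, adjusted p = 6.04e-34; adjusted p = 0.330 with an estimated correlation), interleukin-17 response (-0.87, adjusted p = 0.0113; adjusted p = 0.590 with an estimated correlation) and wound-activated keratinocyte genes (-0.46, adjusted p = 0.0351; adjusted p = 0.670 with an estimated correlation). Over all genes 0 members passed, and adjusted over the list alone 10 cell cycle, 5 epidermal, 2 hair lineage, 1 fibroblast, 11 immediate early, 2 interleukin-17 and 0 wound genes passed. The hair lineage call ended without Treg-sufficient replicate 1 (median 0.25, adjusted p = 0.372) or Treg-depleted replicate 1 (0.80, 0.133), and its median was 1.31, 1.19, 1.45 and 1.25 without Treg-sufficient replicates 2 and 3 and Treg-depleted replicates 2 and 4. The interleukin-17 call ended without Treg-depleted replicate 2 (-0.07, 0.312) or 4 (-0.64, 0.0682), and the median was -0.46 without Treg-sufficient replicate 3 and -1.38 without Treg-depleted replicate 3. The wound call ended without Treg-sufficient replicate 2 (-0.51, 0.117) or 4 (-0.24, 0.424) or Treg-depleted replicate 2 (0.26, 0.862) or 4 (-0.38, 0.0907), and its median was -1.04 without Treg-sufficient replicate 1 and -0.74 without Treg-depleted replicate 1. The cell cycle median was 0.74 and 1.92 without Treg-depleted replicates 1 and 2, the fibroblast median 0.77 without Treg-sufficient replicate 1 and the epidermal median 0.94 without Treg-sufficient replicate 2. Of the 100 genes called in experiment 1, 65 had the same sign in experiment 2, against 55.2% of all genes tested. Their median absolute log2 fold change was 1.79 in experiment 1 and 0.16 in experiment 2.

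**Figure D4:**
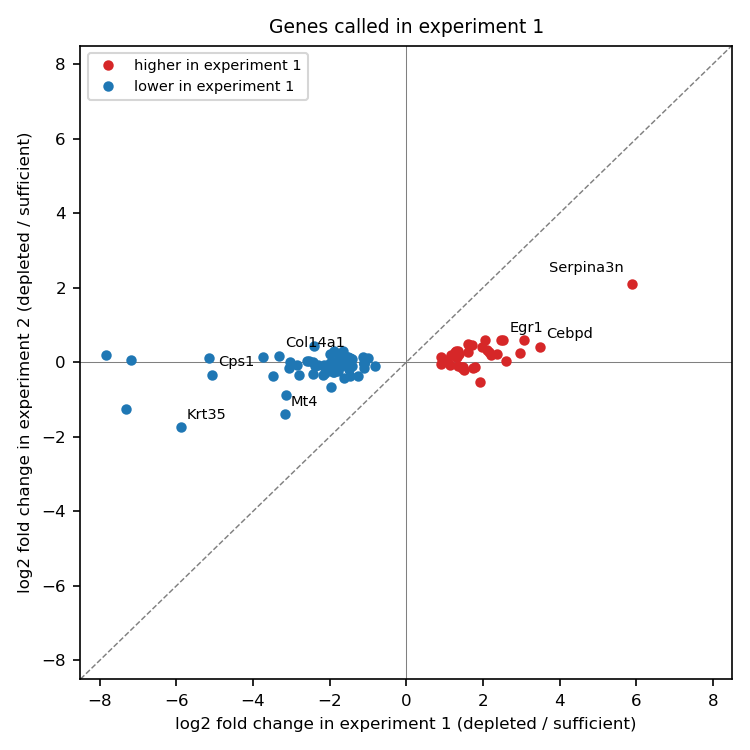
Log2 fold changes (Treg-depleted minus Treg-sufficient) of the 100 genes called in experiment 1, with experiment 1 on the x axis, experiment 2 on the y axis and the dashed line marking equal effects. Most points lie close to 0 on the y axis, where the median absolute value is 0.16, and Serpina3n (5.89 in experiment 1) and Krt35 (-5.88) lie farthest out among the labelled genes, with 3 unlabelled genes at lower values of x.

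Between experiments, where a batch and a biological difference cannot be told apart, melanocyte, hair lineage and cell cycle genes were higher and class I histocompatibility, basal keratinocyte and wound-activated genes lower as groups in experiment 2 than in experiment 1, at the preset correlation. With an estimated correlation each of these lists had an adjusted p of 0.257 or above. By edgeR 268 genes passed, 149 higher and 119 lower in experiment 2, and 3633 had an unadjusted p under 0.05 where chance gives 825. Melanocyte markers were higher (8 of 9 positive, median 2.48, camera adjusted p = 1.41e-09; adjusted p = 0.278 with an estimated correlation). Of them 4 rose over all genes and 8 adjusted over the list alone. The 4 were the pigment enzyme genes Dct (2.48, SE 0.35; adjusted p = 0.0439) and Tyrp1 (2.64), the melanosome gene Pmel (2.52) and the receptor gene Kit (2.51). Hair lineage genes rose as a group (median 1.20, adjusted p = 3.58e-10; adjusted p = 0.257 with an estimated correlation and 0.0481 by fry). Of them 3 passed over all genes (Dlx3 2.14, Krt28 2.54, Krt71 2.27) and 7 adjusted over the list alone. Cell cycle genes were higher too (38 of 38 positive, median 1.14, adjusted p = 6.10e-22; adjusted p = 0.306 with an estimated correlation). Of them 0 passed over all genes and 34 adjusted over the list alone. Their scores differed most in Treg-depleted libraries: -1.778 and -0.657 in experiment 1, 0.292 and 0.624 in experiment 2. In Treg-sufficient libraries they were 0.384 and -0.129, then 0.83 and 0.433. This difference thus holds part of the fall in Treg-depleted libraries of experiment 1 given above. Hair lineage scores also differed more in Treg-depleted libraries. The hair lineage median was 1.93 without Treg-sufficient replicate 1.

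Lower in experiment 2 were MHC class I genes (14 of 14 negative, median -0.66, adjusted p = 2.45e-10; adjusted p = 0.278 with an estimated correlation). H2-K1 (-1.03), H2-D1 (-0.77) and H2-Q7 (-1.42) passed over all genes and 12 members adjusted over the list alone. Basal keratinocyte genes fell (13 of 15 negative, 14 with upper-quartile factors, median -0.46, adjusted p = 9.24e-06; adjusted p = 0.257 with an estimated correlation). The integrin gene Itgb4 (-0.90) and Thbs1 (-1.56) passed over all genes, against 1 higher and 7 lower adjusted over the list alone. Wound-activated genes (median -1.10, adjusted p = 8.88e-07; adjusted p = 0.278 with an estimated correlation; Tgfa, -1.10, and 10 adjusted over the list alone) were lower. Interleukin-17 response genes (15 of 15 negative, median -1.26, adjusted p = 6.08e-06; adjusted p = 0.257 with an estimated correlation; Il17rc, -0.93, and 7 adjusted over the list alone) were lower too. So were the interferon response (23 of 32 negative, 24 with upper-quartile factors, median -0.54, adjusted p = 0.00325; adjusted p = 0.584 with an estimated correlation; 0 over all genes, and 1 higher and 2 lower adjusted over the list alone) and glycolysis and hypoxia (median -0.28, adjusted p = 2.35e-04; adjusted p = 0.278 with an estimated correlation; 0 over all genes and 9 adjusted over the list alone). The regulatory T cell list was lower (4 of 4 negative, median -0.53, adjusted p = 0.0422; adjusted p = 0.278 with an estimated correlation; 0 over all genes and 2 adjusted over the list alone). The interferon call ended without Treg-sufficient replicate 3 (adjusted p = 0.101) or Treg-depleted replicate 1 (median -0.24, adjusted p = 0.0995). The regulatory T cell call ended without Treg-sufficient replicate 2 (0.0639) or 3 (0.101) or Treg-depleted replicate 1 (0.0654). The glycolysis median was -0.43 without Treg-sufficient replicate 3 and -0.10 without Treg-depleted replicate 2, and the wound median -1.71 without Treg-sufficient replicate 4.

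Single genes with the largest increases in experiment 2 were the collagen VI gene Col6a3 (log2 difference 4.48, SE 0.65), Adamts20 (4.09), Gfra3 (3.69), Nmnat2 (3.20), Ptgds (3.10), Spata13 (2.95), Gnmt (2.91) and the transcription factor gene Myb (2.75). The largest decreases were those of Fcgbp (-3.32, SE 0.56), Ptprn2 (-3.06), the complement inhibitor gene Serping1 (-2.57), Gsdmc (-2.52), S100a4 (-2.49), Ltbp2 (-2.41), Scube2 (-2.37), Serpina3i (-2.19), Slco2a1 (-2.18) and Cemip (-2.15). From lists that did not pass, the basement membrane collagen genes Col4a1 (1.68) and Col4a2 (1.04), Tagln (2.53), the Notch target Hes1 (0.93), the stem cell regulators Tcf7l1 (0.78) and Id4 (1.17), Ccnd1 (0.85) and Grhl3 (0.98) rose. Postn (-1.90), Krtdap (-1.60) and Ccn2 (-1.59) fell. The count of 268 was 651, 0, 39 and 6 without Treg-sufficient replicates 1 to 4 (366, 0, 33 and 5 of them higher), 2, 0, 3 and 0 without Treg-depleted replicates 1 to 4 (0, 0, 1 and 0 higher) and 2 (0 higher) without both libraries that held Xist reads. With upper-quartile factors it was 216, and the majority turned (101 higher, 115 lower). With limma-voom it was 296 (155 higher, 141 lower). It was 2025 (1118 higher) with DESeq2, 2443 (1282 higher) without the filter on low counts and 1058 (638 higher) in the model with 4 groups.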

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

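The tests of the female library, of the shallow library, of clock genes and of glucocorticoid targets without Errfi1, the permutations within experiments and the lists with each library left out were chosen only after the result they bear on was seen. After their values were seen, the reading of the hair lineage correlation, of the glucocorticoid targets and of the clock genes was also made stricter, which left each of these explanations open: under the first rules the first and the second would have counted as supported and the third as excluded. The medians of the hair lineage and cell cycle lists were known before their correlation was computed. The outlying libraries were found by comparing the gap of the highest or lowest of 4 libraries with the group's range (Dixon's test at the 95% level). This was exceeded in 14 of 314 groups of 4 tested, where chance gives about 15.7, or 1 in 20.

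Cell cycle genes were lower in Treg-depleted libraries of experiment 1 (median log2 fold change -1.42) and much less so in experiment 2 (-0.19), a difference with adjusted p = 7.05e-25 at the preset correlation and 0.590 with an estimated one. The median in experiment 1 was -1.69 (quartiles -1.90 and -1.05) without the female library Treg-sufficient replicate 2 and -2.19 (quartiles -2.35 and -1.49) without Treg-depleted replicate 2, the only Treg-depleted library of experiment 1 with a lower total than its controls, which argues against either library as the whole cause, though the median was -0.98 without Treg-depleted replicate 1, and the median difference between experiments 0.74 in place of 1.19. Thinning all libraries to 22330729 counts gave -1.40 but was void as a test of depth, since it moved the list's members by a median of only 0.00984 and all genes by 0.0181. A candidate explanation that stays open is that follicles were at a resting stage in the Treg-depleted libraries of experiment 1: over the 8 libraries the hair lineage score followed the cell cycle score (Spearman's rho = 0.786, Pearson's r = 0.890), with a two-sided exact permutation p of 0.141 for rho and 0.0347 for r over the 576 orderings within experiments, and of 0.0279 and 0.00188 over all 40320 orderings (1 relation computed). The relation did not hold in both experiments (rho 1 in experiment 1 and 0 in experiment 2, 4 libraries each), it weakened to rho 0.486 and r 0.742 without Treg-depleted replicates 1 and 2, and both lists were already known to be lower in the same libraries.

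Immediate early genes were higher in Treg-depleted libraries (mean log2 difference 1.29, two-sided exact permutation p = 0.0556 within experiments, the smallest possible, adjusted p = 0.0926 over 5 lists), more so in experiment 1 (adjusted p of the difference between experiments 6.04e-34 at the preset correlation and 0.330 with an estimated one). Stress during dissociation and sorting may have raised them and stays open: 16 heat shock and protein folding genes outside the list had a median of 0.07 and a mean of 0.12 (exact permutation p = 0.167 within experiments, adjusted p = 0.167). Glucocorticoid exposure stays open as well: 19 measured targets had a median of 0.32, which met the rule written beforehand for the whole list (median above 0.3, exact permutation p = 0.0286 over 70 assignments), but within experiments the exact permutation p was 0.0556 (adjusted p = 0.0926), and without Errfi1, which had already been seen, the median of the other 18 was 0.28 (exact permutation p = 0.0556 within experiments, 14 of 18 positive). A different time of day at collection could not be excluded either. Clock genes that peak with Per1 and Nr1d1 had a mean of 0.29 (exact permutation p = 0.0556 within experiments, adjusted p = 0.0926). Over all 70 assignments their exact permutation p was 0.2, with a 95% interval of -0.32 to 0.8. Clock genes of the opposite phase had a mean of 0.26 (exact permutation p = 0.167 within experiments and 0.171 over 70 assignments). A shift of the clock would move these lists apart. An effect of the depletion itself on these genes cannot be told apart from these 3 explanations here, and 36 assignments allow no p under 0.05 for any of the lists. The female library Treg-sufficient replicate 2 had the lowest immediate early score (-1.673, other Treg-sufficient libraries -0.459 to -0.133). Without it the median log2 fold change of the list between conditions was 0.81 in place of 1.14, with 0 of 22 members negative.

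Xist stood at 2713 CPM in Treg-sufficient replicate 2, against 0.968 to 1.69 CPM in the other Treg-sufficient libraries, and at 72 CPM in Treg-depleted replicate 2, against 1.08 to 2.26 CPM in the other Treg-depleted ones. Reads of Treg-sufficient replicate 2 carried into Treg-depleted replicate 2 are a candidate explanation of the second value, and so are a few female cells in that sample. The test for carried reads was void: 0 genes other than Xist marked Treg-sufficient replicate 2 well enough to be looked for, so the 2 cannot be told apart.

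Other libraries stood apart from the rest of their group in single values. Treg-depleted replicate 2 held counts for 18605 genes, against 22670 to 23062. The next lowest library, Treg-sufficient replicate 3 (19593 genes), was not flagged by this test. The upper hair follicle score was 0.398 in Treg-sufficient replicate 2 (others -0.05 to 0.02) and the MHC class II score 1.38 in Treg-depleted replicate 1 (others -0.09 to 0.03). In Treg-sufficient replicate 2, Apcdd1 stood at 60.8 CPM (others 78.5 to 81.6), Hmgcs1 at 281 CPM (others 378 to 394) and Thbs1 at 1640 CPM (others 506 to 661). In Treg-depleted replicate 1, Gata3 stood at 124 CPM (others 81.8 to 83.9), Steap4 at 602 CPM (others 243 to 283) and Hmgcs1 at 213 CPM (others 304 to 320). Cebpd stood at 8.21 CPM in Treg-sufficient replicate 1 (others 3.61 to 3.65), and Treg-sufficient replicate 4 had Adamts20 at 44.2 CPM (others 2.56 to 7.47) and Tagln at 55.1 CPM (others 8.81 to 15.1).

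The other lists whose response differed between the experiments at the preset correlation were epidermal terminal differentiation (adjusted p = 6.61e-13), fibroblast markers (1.05e-05), hair lineage differentiation (0.0045), interleukin-17 response (0.0113) and wound-activated keratinocyte genes (0.0351). With an estimated correlation the adjusted p was 0.330 or above for each. At the preset correlation the hair lineage call ended without replicate 1 of either condition (0.372 and 0.133 for Treg-sufficient and Treg-depleted). The interleukin-17 call ended without Treg-depleted replicate 2 (0.312) or 4 (0.0682), and the wound call without Treg-sufficient replicate 2 (0.117) or 4 (0.424) or Treg-depleted replicate 2 (0.862) or 4 (0.0907).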

How the results depend on the processing

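The fits without both libraries that held Xist reads, the mean effect of the 4-group model, the medians of lists between conditions and the lists within and between experiments with each library left out (given beside those lists in the comparisons) were chosen only after the data were seen. Of the 96 counts of genes recomputed, 62 stayed the same or within 1.5 times the main value and 34 moved. Most of the 62 were counts of 0 that stayed 0. The counts of 100 in experiment 1 and 268 between experiments moved whichever single library was left out. Of the list results, 331 kept direction and side of the threshold, 16 gained a call, 34 lost one and 38 reversed, and of the named gene results 1642 kept both, 64 gained a call, 504 lost one and 53 reversed. Immediate early, cell cycle, hair lineage and cholesterol lists kept their direction in 14 of 14 alternatives and their call in 12, all but the estimated correlation and fry. The scaling moved the median of all genes by at most 0.052 log2 in any comparison. Except where a clause says otherwise, the cause was not tested. The pseudocount and the alternatives for the authors' own results were not run, because the values are raw counts. Depth limits the values of genes at a few counts per library, such as Foxp3.

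The library letters do not pair the samples: same-letter correlations of the deviations were 0.179, 0.13, 0.094 and 0.314. With the letters as replicate block Foxp3 had a log2 fold change of -0.136, and without the experiment number (no replicate block) Foxp3 had -0.025 and B2m -0.005, the adjusted p was 0.0916 for MHC class I, which lost its call, and 0.952 for migration and matrix, which reversed. Either way 0 genes passed between conditions.

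With DESeq2 the counts were 90 between conditions, 708 in experiment 1, 2 in experiment 2, 186 for the interaction and 2025 between experiments, with Sox9 at -0.007 and B2m at -0.009. Limma-voom gave Foxp3 -0.346, and 82 genes in experiment 1, most of them higher. DESeq2 size factors gave Sox9 -0.006 and B2m -0.008, upper-quartile factors -0.007 and -0.005 (and 216 genes between experiments, most of them lower), and a CPM of at least 1 in 4 libraries -0.005 and -0.006. With no filter on low counts the counts were 820, 1152, 132, 534 and 2443, and Sox9 and B2m were -0.011 and -0.009; the median prior degrees of freedom were infinite there, against 3.77 with the filter. At an adjusted p under 0.1 experiment 1 had 296 and the difference between experiments 1603 genes, and with an absolute log2 fold change of at least 1 the latter had 156. The 4-group model gave 1058 genes between experiments, and an adjusted p of 0.991 for neutrophil and 0.0555 for endothelial markers.

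Experiment 1 alone reversed Lgr5 (-0.201), Sox9 (-0.117), Foxp3 (-0.886) and B2m (-0.038). Experiment 2 alone reversed Krt15 (0.072), Krt10 (0.587), Ivl (1.108), Gata3 (-0.189), Col5a1 (0.061) and Egfl7 (0.065). Between conditions Col5a1, Egfl7 and Sparc were lower in the main fit and in 20 of 21 alternatives each. Their log2 fold changes ran from -1.678 to 0.061, -0.834 to 0.065 and -0.479 to 0.023. Each alone gave 0 genes between conditions.

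Without both libraries that held Xist reads there were 2 genes between experiments, 487 in experiment 1 and 89 for the interaction, where experiment 1 keeps 1 library per condition, assumed to vary like those of experiment 2, which alone give the spread within groups; Krt10 (0.236), Ivl (0.544) and Sparc (0.023) reversed. The adjusted p of lists was then 7.19e-05 for epidermal differentiation, 0.000201 for wound-activated, 0.457 for interleukin-17, 2.28e-05 for interferon, 0.964 for Notch, 0.619 for Wnt, 0.837 for BMP and TGF-beta, 0.049 for sebaceous and 0.174 for glycolysis genes, and 0.964 for macrophage and Langerhans cell, 0.222 for neutrophil, 0.0509 for fibroblast, 0.174 for endothelial and 0.0118 for melanocyte markers.

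With an estimated correlation the adjusted p was 0.331 for hair lineage, 0.488 for interleukin-17, 0.856 for MHC class I, 0.579 for MHC class II, 0.488 for cell cycle, 0.579 for cholesterol, 0.41 for immediate early, 0.488 for fibroblast and 0.41 for endothelial lists, and by fry 0.302, 0.436, 0.787, 0.48, 0.436, 0.436, 0.302, 0.436 and 0.302 in the same order, so that 0 lists were called. Over genes with a mean normalized count of at least 50 the adjusted p was 0.0236 for interferon, 0.963 for migration and matrix, 0.924 for macrophage and Langerhans cell and 0.552 for endothelial lists.

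Leaving out each library in turn, the log2 fold change ran from -0.046 to 0.215 for Lgr5, -0.105 to 0.127 for Sox9, -0.72 to 0.205 for Krt10, -0.523 to 0.321 for Ivl, -0.104 to 0.166 for Gata3, -0.308 to 0.627 for Foxp3, -0.24 to 0.057 for Krt15, -0.125 to 0.124 for B2m and -0.048 to 0.236 for H2-K1. The counts ran from 0 (without Treg-depleted replicate 3) to 442 (without Treg-depleted replicate 2) in experiment 1, from 0 (without Treg-sufficient replicate 2, Treg-depleted replicate 2 or 4) to 651 (without Treg-sufficient replicate 1) between experiments and from 0 to 9 (without Treg-sufficient replicate 1) for the interaction.

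The adjusted p of lists with each library left out ran from 8.1e-06 to 0.273 (without Treg-depleted replicate 2) for interleukin-17, 0.000228 to 0.478 (without Treg-sufficient replicate 1) for MHC class I, and, with the highest value without Treg-depleted replicate 1, 0.000106 to 0.136 for MHC class II, 0.000647 to 0.0797 for fibroblast and 0.0125 to 0.109 for endothelial markers. Calls were also lost without Treg-depleted replicate 1 for MHC class I (0.474), without Treg-depleted replicate 2 for fibroblast and endothelial markers (0.0748 each) and without Treg-sufficient replicate 2 (0.0804) or 3 (0.0711) for endothelial markers. Calls appeared at the lower end for wound-activated (3.6e-05 to 0.872), interferon (3e-05 to 0.984) and sebaceous genes (0.00396 to 0.671) without Treg-depleted replicate 2, epidermal differentiation (0.0138 to 0.98) without Treg-sufficient replicate 2, migration and matrix (0.0168 to 0.827) without Treg-sufficient replicate 3, and basal keratinocyte (0.0139 to 0.904) and melanocyte lists (0.000786 to 0.804) without Treg-sufficient replicate 4. The interferon call also appeared without Treg-sufficient replicate 2 (0.00791) or 4 (0.00666), and the melanocyte call without Treg-depleted replicate 2 (0.0289). No call appeared for Wnt (0.27 to 0.912), BMP and TGF-beta (0.109 to 0.999), Notch (0.474 to 0.904), upper follicle (0.0896 to 0.921), glycolysis (0.136 to 0.998), neutrophil (0.27 to 0.99), macrophage and Langerhans cell (0.474 to 0.904) or red blood cell lists (0.478 to 0.998).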

Other observations

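The lists of clock genes, of heat shock genes and of glucocorticoid targets were written after the immediate early result was seen, and the count of splits that give as many genes between conditions was chosen only after that result was seen. Among clock genes, Nr1d2, a repressor of the same family as Nr1d1, had a log2 fold change of 0.62 between conditions (SE 0.16, unadjusted p = 0.00392, edgeR adjusted p = 0.686), Tef 0.61 (SE 0.19) and Per2 0.75 (SE 0.41). Nfil3, which opposes these in the clock, had 0.81 (SE 0.22, edgeR adjusted p = 0.686) and the core activator gene Arntl 0.14 (SE 0.13). These genes were chosen after their values were seen, and none of them passed.

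The 8 libraries can be split into groups of 4 in 35 ways. The 9 lists called between conditions at the preset correlation were matched or exceeded by other splits, since 20 of the 35 gave as many, with 14 lists at the highest other, so chance could not be excluded for these calls. Among the 18 splits with 2 libraries of each experiment on each side 11 gave as many, and the highest other gave 12. For single genes between conditions the real split and the highest other both gave 0, so all 35 gave as many and the comparison says nothing. Between experiments the real split gave 268 genes and the highest other 0. Only the real split, 1 of 35, gave as many, but the 35 splits ignore that each experiment holds 2 libraries of each condition. Splits that keep this balance number 18, too few for a share under 0.05, so chance was not excluded by them. The count was 651, 0, 39 and 6 without Treg-sufficient replicates 1 to 4, and 2, 0, 3 and 0 without Treg-depleted replicates 1 to 4.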
